A study of Mus musculus with 8 samples.

How the data were processed

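The series holds 8 poly(A) RNA libraries from established mouse leukaemia lines of strain 129S6, which carry MLL-AF9 and CreER. The 4 groups are floxed or wild type Cdc73, each after 24 or 48 h of 7.5 nM 4OHT, with 2 biological duplicates per group. Per the labels' protocols, cells grew in IMDM with serum and interleukin 3, RNA was extracted with a Qiagen RNeasy kit, and libraries were sequenced on the Illumina HiSeq platform. Per the submitters' processing notes, Bowtie2, Cufflinks 2.1, Cuffdiff and the build mm10 were used, with no role or order given. Strandedness, trimming, duplicate removal and the annotation used for counting are not given in the sources used here.

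Per the file headers, the authors' deposited table holds 1 FPKM value per gene for each of the 4 groups, with the duplicates already combined. It also holds the authors' q-value for floxed against wild type cells at each time, and the authors' fold for each time. The last column repeats the 24 h name for the fold, and was taken as the 48 h fold because it equals the ratio of the 48 h FPKM values within 0.1% for 14820 of 14823 genes above 0 in both groups, while the 24 h column equals the 24 h ratio for 14787 of 14789. FPKM is scaled to transcript length and library size, so it is relative to all other RNA, and a change of total RNA per cell is not seen in it. The table does not say whether both times were scaled in 1 run, so levels and folds across times are given as values, without a call.

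The table lists 23361 genes, of which 5945 are at 0 in all 4 groups. A gene was taken as expressed at 1 FPKM or more in at least 1 group, which left 11158 genes. Left out were 27 genes whose names had been turned into date numbers, 19 of them at that level. Genes were matched by symbol and locus to GENCODE M21, which uses the same assembly as mm10, and 10472 expressed genes had a match (coordinates are 1-based and from this annotation). Among all genes, 4353 share their locus entry with another gene, and reads of overlapping or near-identical genes may have been split unevenly between them, so such genes are uncertain. Expressed genes included 211 small RNAs, which poly(A) libraries and length scaling measure poorly, and 71 pseudogenes.

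Depth per library is not given. Relative depth was estimated from low FPKM values, on the assumption that the most common ratio between groups, over genes under 0.05 FPKM in both, comes from genes with 1 fragment in each. Few genes lie at that ratio, and the assumption was not tested. Under it the ratio is the relative worth of 1 fragment after the authors' scaling, and a lower worth means more depth. At 24 h it was 0.836 in floxed over wild type cells, with 64 of 1274 genes within 0.002 of it. At 48 h it was 1.07, with 41 of 995 genes. Between the times it was 0.991 in wild type cells and 1.27 in floxed cells. The sums of FPKM were 665619, 656874, 653299 and 699193 in wild type and floxed cells at 24 h and wild type and floxed cells at 48 h. The 10 highest genes held 9.30% of the sum in floxed cells at 48 h and at most 7.04% in the other groups. With no counts per library, no interval or detection limit was computed.

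The design fixed before the data were examined was a limma fit over 8 libraries with gene set tests by camera. It could not be run on 1 value per group, so the authors' q under 0.05 was used as the call of a gene, and no standard error or replicate check of a gene's change was made. The test behind the q is the authors', on 2 libraries per group. The 1 value per group leaves no test of the difference between the times or of the change of the genotype difference with time, so genes of at least 2-fold are counted there as sizes only. The genotype comparison at each time, the change of that difference, the comparison of times in each line and the overlap of calls were the comparisons made. Fold values in the text are ratios of the deposited FPKM, given only where both groups reach 1 FPKM. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The direction of a call is that of the FPKM values.

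For counts adjusted over a list alone, p was recovered from the authors' q as q times rank over the number of tested genes (q under 1: 11927 genes at 24 h and 12192 at 48 h) and adjusted again by the Benjamini-Hochberg method. The recovered p were whole multiples of 5e-05, within 0.01 of a multiple, for 99.9% or more of those under 1000 multiples. On simulated values for the 11158 expressed genes, 97.3% of 4644 genes with q under 0.5 gave back their p. For the rest, 125 whose q came from the running minimum of the adjustment and 1 tied by rounding, the p was too high by at most 0.237%, and all 11158 calls were the same.

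Gene lists were described by the percentile of their median log2 change among 10000 random lists of the same size drawn from the same 20 bins of mean expression, for lists with at least 5 expressed members. A list outside percentiles 2.5 to 97.5 is said to stand apart. This describes these groups and is not a p-value, and correlation among the genes of a list is not allowed for. On simulated values of the 11158 genes, 6 of 100 unchanged lists stood apart, and 60 of 60 lists changed by 1.25-fold did, as did 60 of 60 each at 1.5-fold and 2-fold. The simulated noise was independent between genes and only as large as that between the wild type groups. There the median absolute log2 change was 0.06, against 0.21 and 0.47 between genotypes at 24 h and 48 h. At 48 h the random range for the 25 mitosis genes was -0.38 to 0.21, so a list within its range may still have changed by 1.25-fold. Fixed before the data were examined were 26 lists: PAF1 complex, elongation factors, MLL fusion programme, Myc targets, DNA replication, mitosis, replication-dependent histones, p53 targets, interferon response, amino acid and ER stress, immediate early genes, cholesterol synthesis, ribosomal proteins, respiratory chain, glycolysis, and stem and progenitor, granulocyte, monocyte and macrophage, mast cell and basophil, erythroid, megakaryocyte, B cell, T and NK cell, dendritic cell and MHC class II, stroma and sex-linked genes. Of these, 19 had enough members. After the data were seen 5 lists were added: eosinophil granule, S100 and stefin, and MHC class I genes, cell cycle inhibitors, and D type cyclins with their kinases.

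The genes named were chosen by a rule written beforehand. It takes Cdc73, then for each genotype comparison the 8 called genes with the largest log2 change each way among those of at least 5 FPKM in a group, for a list standing apart up to 4 called members by size in its direction, and for other lists the 3 members with the highest mean level. For the comparisons of times it takes the 5 largest each way. Predicted genes, pseudogenes and small RNAs were skipped. The rule's condition that libraries of the groups do not overlap could not be applied, and genes of the change between times had to be called at 24 h or 48 h. Of the added lists every expressed member counts as named. Some genes the rule takes are not reported here. Genes outside the rule are marked in the text as chosen after their values were seen.

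Alternatives were a pseudocount of 0.1 or 5, no filter on low values or at least 5 FPKM, values rescaled to the same sum in every group, quantile normalization, TMM factors computed on the values without weights, and q under 0.05 with a log2 change of at least 1. Added after the data were seen were q under 0.01, p adjusted over both times together, and leaving out small RNAs, pseudogenes and genes sharing a locus entry, or the genes of similar large difference at both times. Intervals of shares are exact binomial limits at 95%, and intervals of differences between gene groups are percentiles of 1000 bootstrap draws over genes (10000 for list medians). The difference between long and short genes was tested on simulated values of 10472 genes: -0.50 put in came back as -0.50, and 3.15% of a trend made from mRNA length was left within bins of mRNA length. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.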

Results

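Poly(A) RNA was sequenced from mouse acute myeloid leukaemia lines of strain 129S6, made by introducing the fusion oncogene MLL-AF9 into bone marrow cells. In the floxed line Cdc73 was flanked by recombination sites. Cdc73 encodes a subunit of the PAF1 complex, which travels with RNA polymerase II during transcription elongation. The other line was wild type for Cdc73. Both lines carried CreER, a recombinase that enters the nucleus when it binds 4-hydroxytamoxifen (4OHT), and both were treated with 7.5 nM 4OHT for 24 or 48 h. The 8 libraries formed 4 groups of 2 biological duplicates, and the comparison of genotypes asks what excision of Cdc73 changes in these cells. The authors' deposited table gives 1 FPKM value (fragments per kilobase of transcript, scaled to library size) per gene and group, so levels below are the authors' group values, with no SD or n, and a call is a q under 0.05 in that table. Total reads are not given. If the most common ratio of low values comes from single fragments, which was not tested, 1 fragment was worth 0.836 times as much FPKM in floxed as in wild type cells at 24 h and 1.07 times at 48 h, where a lower worth means more depth. The floxed and wild type cells are different lines and no untreated library was analysed here, so differences that existed before 4OHT are part of every genotype comparison.

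Cdc73 itself was lower in floxed cells at both times. The gene lies on chromosome 1 from 143598800 to 143702893 on the minus strand of mm10 (ENSMUSG00000026361.9). Its FPKM was 26.2 in wild type and 5.96 in floxed cells at 24 h, and 26.9 and 5.45 at 48 h, which is 22.7% and 20.3% of the wild type level. The authors' deposited table gives q = 0.000449 and q = 0.000165 for these differences. Each is the smallest q it holds at that time, and 1328 genes have it at 24 h and 3684 at 48 h. The value covers the whole gene, another gene shares its locus entry, and the excised part is not given in the sources used here, so the remaining level does not measure the share of cells that kept the gene. Of the 6 PAF1 complex subunits, 2 were called higher and only Cdc73 lower at each time, and 3 were called at each time when adjusted over the list alone. Paf1, which names the complex, was 1.49-fold higher at 24 h and 1.88-fold higher at 48 h. Ctr9 stood at 29.5 in wild type and 33.1 in floxed cells at 24 h, and Wdr61 at 64.4 and 67.9, with no call for either. The list as a whole stayed within the range of random lists matched on expression, with a median log2 change of 0.20 at 24 h (percentile 94.6) and 0.08 at 48 h (percentile 73.7), the latter -0.01 (percentile 73.9) with groups rescaled to the same sum.

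At 24 h, interferon response genes were lower in floxed cells, and immediate early genes, p53 targets and several elongation factors were higher. Ifi27l2a, an interferon-induced gene, was 7.28-fold lower, at 40.0 FPKM in wild type and 5.49 in floxed cells. Isg15, a ubiquitin-like protein that marks the interferon response, stood at 7.67 and 0.831, and Oasl2, a member of the antiviral oligoadenylate synthetase family, at 2.68 and 0.0456. Hexim1, which holds the elongation kinase P-TEFb inactive, was 2.68-fold higher, and Rnf20, a ligase for histone H2B in the same pathway as the PAF1 complex, 1.66-fold higher. Cdkn1a, a cell cycle inhibitor induced by p53, was 2.26-fold higher. In all, 3037 of 10987 tested genes (27.6%) were called at 24 h, 1473 higher and 1564 lower, and 347 of the called genes differed by at least 2-fold on the log2(FPKM + 1) scale. That last count was 657 with a pseudocount of 0.1 and 119 with a pseudocount of 5. The median log2 change over all 11158 expressed genes was -0.01.

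Some of the largest single differences at 24 h were in granule and surface genes. Prg2, the major basic protein of eosinophil granules, was 47.7-fold higher, at 1.94 in wild type and 92.6 in floxed cells. Ear11, an eosinophil-associated ribonuclease, stood at 0.711 and 61.7, and Car4, a membrane carbonic anhydrase, was 29.8-fold higher. BC117090, a stefin-like gene, was 53.2-fold higher, while Stfa1, a cysteine protease inhibitor of the stefin A family, was 245-fold lower, at 361 and 1.48 FPKM. St6galnac2, a sialyltransferase, stood at 0.0497 and 26.4, and BC018473 at 0.0417 and 38.6. AA465934 was 55.0-fold higher, Ndufs5 12.2-fold lower, H2-T23 11.2-fold lower and Nrp2 9.47-fold lower. BC002163 stood at 0.577 and 40.3, Mid1 at 9.15 and 0.221 and Rnaset2b at 5.39 and 0.0770. These last 7 genes share their locus entry with another gene, so how reads were split there is uncertain, as it is for the stefin family and for Gadd45a, Msi2, Elane and BC035044, which share an entry too.

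The interferon, p53 and elongation genes named above for 24 h were taken as members of gene lists fixed beforehand. The lists are therefore not separate support for them. Of 25 expressed interferon response genes, 17 were lower and 0 higher (19 called when adjusted over the list alone), and the median log2 change of -1.03 lay below all 10000 random lists matched on expression. Of 22 immediate early genes, 15 were higher and 0 lower (17 over the list alone), with a median of 0.61 at percentile 100. With a pseudocount of 5 these medians were -0.50 and 0.35, at percentiles 0 and 100. Fos, Junb and Ier5, transcription factors and a regulator induced within minutes of a stimulus, were 5.22-, 2.53- and 3.09-fold higher, and Egr1 stood at 0.172 and 3.19. Of 23 p53 targets, 9 were higher and 0 lower (9 over the list alone; median 0.23, percentile 99.8), among them Gadd45a at 2.61-fold, Btg2 at 2.03-fold and Phlda3 at 1.97-fold. Of 28 elongation factors, 6 were higher and 1 lower (7 over the list alone; median 0.18, percentile 99.9), with Ccnt2, a cyclin of P-TEFb, 1.77-fold and Rnf40 1.33-fold higher. Of 25 amino acid and ER stress genes, 9 were higher and 3 lower (12 over the list alone; median 0.19, percentile 99.9). The higher members included Nupr1 at 2.13-fold, Ppp1r15a at 1.77-fold, Dnajb9 at 1.54-fold and the asparagine synthetase gene Asns at 1.53-fold.

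Progenitor, monocyte, ribosomal and respiratory genes lay on the lower side at 24 h. Of 12 expressed stem and progenitor genes, 7 were lower and 2 higher (9 adjusted over the list alone; median -0.43, percentile 0.01), and the median was -0.28 with a pseudocount of 5 and -0.26 with no filter on low values. Cd48 was 2.29-fold lower, the RNA-binding protein gene Msi2 2.02-fold lower and Meis1, a partner of HOX proteins in leukaemia, 1.65-fold lower, while Angpt1 stood at 1.66 and 0.371. Of 22 monocyte and macrophage genes, 7 were lower and 3 higher (12 over the list alone; median -0.25, percentile 0.03). The chemokine receptor gene Ccr2 was 3.14-fold, Siglec1 3.64-fold and F13a1 2.03-fold lower, and Cd36 stood at 1.19 and 0.212. Respiratory chain genes had 9 lower and 1 higher of 80 (7 over the list alone; median -0.12, percentile 0.03), with Atp5s 1.68-fold, Sdhd 1.46-fold and Ndufb10 1.38-fold lower. The share called was below the 27.6% over all tested genes, and the median came from small differences. Of 78 ribosomal protein genes, 2 were lower and 1 higher (1 over the list alone). Their median of -0.11 (percentile 0.08) came from small differences, and under quantile normalization it was -0.05 and no longer apart from random lists (percentile 18.8). In all, 9 of 19 lists with enough members stood apart at 24 h. No number expected by chance is given, because correlation among the genes of a list is not allowed for.

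At 48 h the difference between the lines was wider, and genes of mature myeloid cells were higher while growth and replication genes were lower. S100a8 and S100a9, calcium-binding proteins of neutrophils and monocytes, were 4.03- and 3.32-fold higher, with S100a8 at 4134 FPKM in wild type and 16678 in floxed cells. Lyz2, the lysozyme of myeloid cells, was 5.68-fold higher at 587 and 3333 FPKM, and Mmp9, a gelatinase of neutrophil granules, 6.67-fold higher. Npm1, an abundant nucleolar protein, was 1.63-fold lower and Kit, the receptor for stem cell factor, 3.16-fold lower. Hexim1 was 5.46-fold higher, at 26.9 and 147 FPKM. In all, 6267 of 11039 tested genes (56.8%) were called, 2842 higher and 3425 lower, of which 1705 differed by at least 2-fold on the log2(FPKM + 1) scale. With a pseudocount of 5 that count was 755. The median log2 change was -0.06 and the median absolute change 0.47, against 0.21 at 24 h.

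The largest single differences at 48 h included several already seen at 24 h. BC117090 was 113-fold, Car4 86.4-fold, AA465934 62.3-fold and Prg2 50.7-fold higher, and Ear11 stood at 0.683 in wild type and 138 in floxed cells. Stfa3, another stefin A gene, was 46.4-fold higher, and Chi3l1, a chitinase-like secreted protein, 47.0-fold higher. Serpinb2, an inhibitor of plasminogen activators, stood at 0.605 and 92.0. Stfa1 was 144-fold lower and Ndufs5 14.0-fold lower. Scd1, which desaturates fatty acids, was 18.8-fold lower, Ramp1, a subunit of a peptide receptor, 12.2-fold lower, and Clec11a, a growth factor for blood progenitors, 11.2-fold lower. BC035044 was 7.81-fold lower, and Dynlt1b stood at 10.0 in wild type and was listed at 0 in floxed cells. Dynlt1b was also far lower in floxed cells at 24 h, without a call, so that difference was not particular to 48 h.

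**Figure D1:**
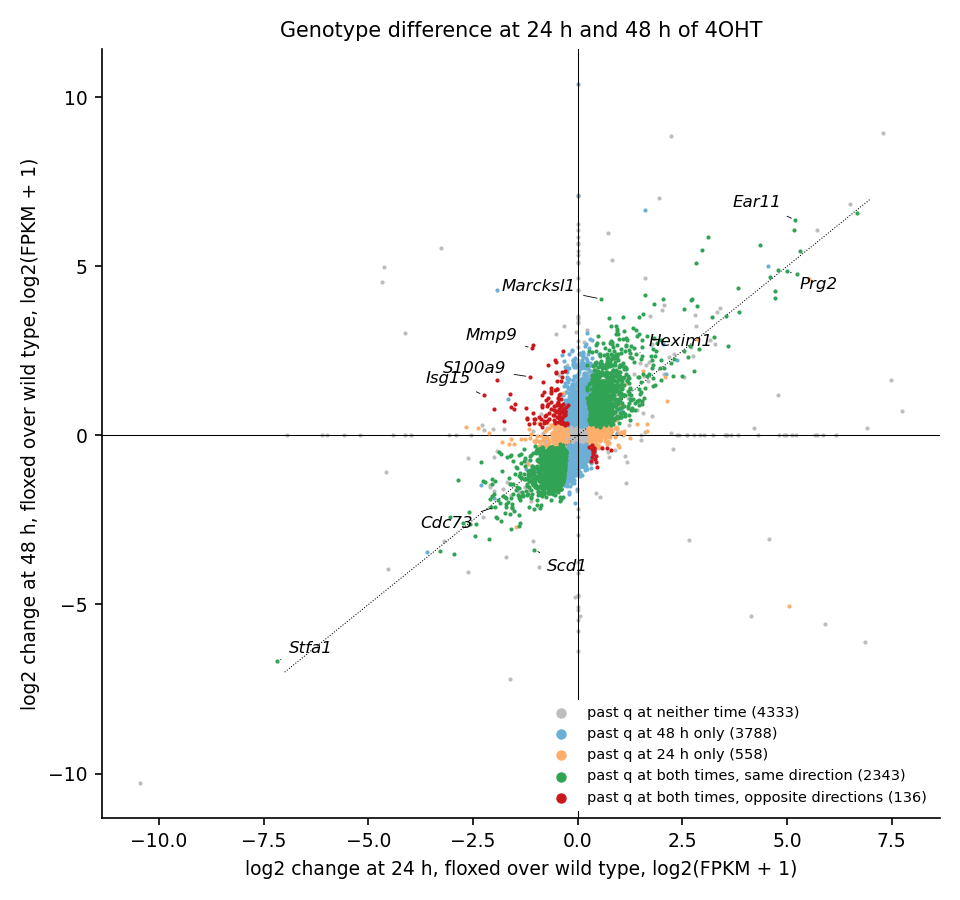
Each point is 1 of 11158 expressed genes, with its log2 change of FPKM + 1, floxed over wild type, at 24 h on the horizontal and at 48 h on the vertical axis, coloured by whether the authors' q was under 0.05 at each time; the dotted line marks equal changes. Of the genes called at both times, 2343 lie on the same side of 0 at both times and 136 on opposite sides, among them S100a9, Mmp9 and Isg15.

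Genes of mature granulocytes and monocytes were higher in floxed cells at 48 h. Of 25 granulocyte genes, 17 were higher and 5 lower (22 adjusted over the list alone; median log2 change 1.23, percentile 100), whereas at 24 h 10 were higher and 7 lower (18 over the list alone; median -0.01, percentile 59.1). Mmp8, a neutrophil collagenase, was 8.34-fold higher, and Retnlg and the chemotactic receptor gene Fpr1 stood at 0.804 and 11.8 and at 0.426 and 8.23. Elane, the elastase of primary granules, was 2.06-fold lower. Of 22 monocyte and macrophage genes, 19 were higher and 2 lower (21 over the list alone; median 1.21, percentile 100), with Lyz1 5.94-fold, Gpnmb 5.92-fold and the lipopolysaccharide co-receptor Cd14 4.77-fold higher. The 2 lower genes were Ccr2 and F13a1, at 0.644 and 0.343 times the wild type level, and both had been lower at 24 h. Stem and progenitor genes had 7 lower and 3 higher (10 over the list alone; median -0.58, percentile 0.59), with Cd48 3.38-fold and Msi2 2.23-fold lower and Angpt1 at 1.53 and 0.187. That list was no longer apart among genes of at least 5 FPKM, where its median was -0.60 (percentile 3.44), and its median was -0.38 with a pseudocount of 5 and -0.30 with no filter on low values.

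Immediate early genes and p53 targets were again higher at 48 h. Of 22 immediate early genes, 19 were higher and 1 lower (20 adjusted over the list alone; median 1.49, percentile 100). Ier5 was 13.3-fold, Fos 10.7-fold, Jun 8.17-fold and Zfp36, which destabilises short-lived mRNAs, 6.13-fold higher. Of 23 p53 targets, 15 were higher and 1 lower (17 over the list alone; median 0.69, percentile 100), among them Cdkn1a at 6.52-fold, Gadd45a at 6.21-fold and Trp53inp1 at 6.60-fold, and Plk2 stood at 0.345 and 11.7. With a pseudocount of 5 the medians of these lists were 0.72 and 0.44. Of 28 elongation factors, 10 were higher and 5 lower (15 over the list alone), but the median of 0.08 was within the random range (percentile 88.3). With groups rescaled to the same sum it was -0.02 at percentile 88.7. That rescaling lowered the median of all genes too, from -0.06 to -0.16. Supt4a, a subunit of the elongation factor DSIF, was 2.74-fold higher and Tcea1, which restarts stalled polymerase, 1.47-fold lower, and Ssrp1 stood at 189 and 179.7 with no call.

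Growth and replication genes were lower at 48 h. Of 55 Myc targets, 33 were lower and 3 higher (38 adjusted over the list alone; median -0.54, percentile 0), against 8 lower and 2 higher at 24 h (8 over the list alone; median -0.01, percentile 58.6). Tmem97 was 3.30-fold lower, the folate carrier Slc19a1 3.16-fold, Exosc5, a subunit of the RNA exosome, 2.24-fold, Sord 2.24-fold and the mitochondrial chaperonin Hspd1 1.88-fold lower. Of 32 DNA replication genes, 17 were lower and 4 higher (21 over the list alone; median -0.40, percentile 1.50), with the DNA polymerase gene Pole 2.32-fold, Mcm6 and E2f1 1.98-fold each and Gins1 1.93-fold lower. Pcna, the sliding clamp of DNA polymerase, went the other way and was 1.84-fold higher. At 24 h that list had 4 higher and 2 lower (6 over the list alone; median -0.04, percentile 40.4). Of 80 respiratory chain genes, 30 were lower and 11 higher (39 over the list alone; median -0.17, percentile 2.31), with Atp5s 2.95-fold, Ndufb4 2.32-fold and Atp5g2 2.17-fold lower. The share called in either direction was below the 56.8% over all tested genes. This last list was near the edge of the random range, and its median ranged from -0.28 under quantile normalization to -0.10 with TMM factors. It was within it with a pseudocount of 5 (-0.14, percentile 5.24), with no filter on low values (-0.17, percentile 2.57) and without the genes of similar large difference at both times (-0.14, percentile 7.17), the latter set chosen after the data were seen.

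Interferon response genes were mixed at 48 h. Of 25, 13 were higher and 4 lower (18 adjusted over the list alone; median 0.31, percentile 85.5), and the median was 0.53 with a pseudocount of 0.1 and 0.18 with a pseudocount of 5. Ifitm3, a membrane protein that restricts viral entry, was 3.67-fold higher, Isg15 2.90-fold higher and the tetherin gene Bst2 1.46-fold lower. Amino acid and ER stress genes had 8 higher and 11 lower (19 over the list alone; median -0.25, percentile 12.1). The stress-induced factor Atf4 was 1.50-fold lower and Psat1, an enzyme of serine synthesis, 1.93-fold lower, whereas the ER chaperone Hspa5 stood at 761 and 704. Ribosomal protein genes had 2 higher and 7 lower of 78 (3 over the list alone; median -0.07, percentile 18.9, but above 0 with TMM factors), and Rplp1 stood at 6167 and 6613. In all, 8 of the 19 lists stood apart at 48 h.

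Genes linked to MLL fusion proteins went both ways. Of 27 expressed, 6 were higher and 5 lower at 24 h (13 adjusted over the list alone; median 0.05, percentile 79.1), and 8 were higher and 13 lower at 48 h (21 over the list alone; median -0.28, percentile 8.27). The median at 24 h was -0.03 with no filter on low values and -0.0089 under quantile normalization, and that at 48 h was -0.16 with a pseudocount of 5 and -0.0090 (percentile 73.1) among genes of at least 5 FPKM. Lmo2, a transcriptional adaptor of blood progenitors, was 1.45-fold lower at 24 h and 1.50-fold lower at 48 h. Myb, a transcription factor of dividing progenitors, was 1.53-fold lower and Mbnl1, a splicing regulator, 1.56-fold lower at 48 h.

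**Figure D2:**
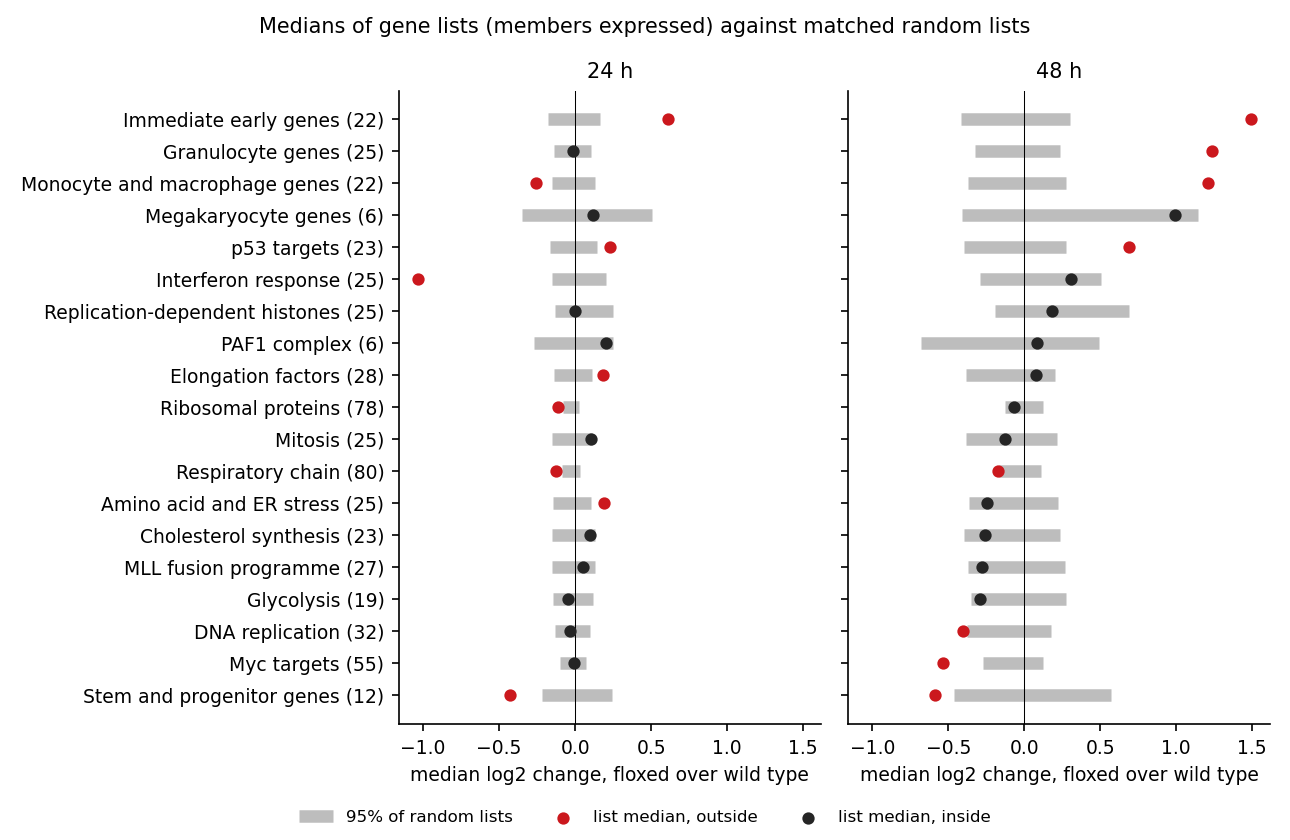
Each dot is the median log2 change of FPKM + 1, floxed over wild type, of the expressed members of 1 gene list (number of members in brackets) at 24 h and 48 h, and each grey bar holds the medians of 95% of 10000 random lists matched on expression. Red dots lie outside their bar, 9 lists at 24 h and 8 at 48 h.

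Other lists stayed within the random range at both times. Mitosis genes had 2 higher and 0 lower of 25 at 24 h (1 adjusted over the list alone; median 0.10, percentile 96.4) and 3 each way at 48 h (5 over the list alone; median -0.12, percentile 41.1), and Birc5, which protects dividing cells from apoptosis, was 1.56-fold higher at 48 h. Replication-dependent histones had 1 higher and 4 lower of 25 at 24 h (5 over the list alone; median -0.00099, percentile 23.9) and 7 higher and 2 lower at 48 h (6 over the list alone; median 0.18, percentile 43.8). The mRNAs of these genes normally end without a poly(A) tail, so poly(A) libraries measure them poorly. The linker histone gene Hist1h1c was 1.33-fold lower at 24 h and 2.19-fold higher at 48 h. Cholesterol synthesis genes had 3 higher and 2 lower of 23 at 24 h (5 over the list alone; median 0.10, percentile 93.8), and 2 higher and 8 lower at 48 h (10 over the list alone; median -0.26, percentile 13.8). Within that list Idi1 was 1.87-fold higher at both times and Fdps 1.76-fold lower at 48 h. Glycolysis genes had 1 higher and 1 lower of 19 at 24 h (2 over the list alone; median -0.04, percentile 34.4) and 1 higher and 7 lower at 48 h (7 over the list alone; median -0.29, percentile 5.80), with the lactate dehydrogenase gene Ldha 1.59-fold lower. At 48 h the histone median ranged from 0.08 to 0.25 over the alternatives and the mitosis median from -0.22 to -0.05. The 24 h medians near 0 of the histone, glycolysis, granulocyte and Myc target lists changed sign under a scaling.

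Markers of other cell types were mostly low. Of 6 megakaryocyte genes, 1 was higher and 1 lower at 24 h (2 adjusted over the list alone; median 0.12, percentile 55.9), and 4 were higher and 1 lower at 48 h (6 over the list alone; median 0.99, percentile 93.5), a call that a pseudocount of 0.1 moved past the range (median 2.74, percentile 99.0). The platelet factor gene Pf4 stood at 0.977 and 10.8 at 48 h. Of 4 mast cell and basophil genes, 2 were higher and 1 lower at 24 h and 3 higher and 1 lower at 48 h (3 and 4 over the list alone), with Hdc, the histidine decarboxylase, 1.35- and 1.50-fold lower and the protease gene Mcpt8 2.77- and 1.68-fold higher. Of 2 B cell genes, Cd79b was higher at both times, at 0.890 and 8.21 at 24 h, and Igll1 lower, at 4.87 and 0.608, and both calls held over the list alone. Of 4 T and NK cell genes, 1 was lower at 24 h (1 over the list alone) and 1 each way at 48 h (2 over the list alone), and Nkg7, a cytotoxic granule protein, was 2.20- and 5.19-fold lower. Of 2 erythroid genes, Gata1 was higher at both times, at 0.174 and 2.08 at 48 h (2 and 1 over the list alone). Of 4 dendritic cell and MHC class II genes, 1 was higher and 2 lower at each time (4 and 3 over the list alone). The invariant chain gene Cd74, which shares its locus entry, was 6.79-fold higher at 48 h. Of 2 stroma genes, 1 was lower at 24 h and both were higher at 48 h (1 and 2 over the list alone), with Acta2 at 3.09 and 7.66. Of the sex-linked genes only Xist, which silences an X chromosome in female cells and shares its locus entry, was expressed. It was called higher in floxed cells at both times, at 4.25 and 17.3 at 24 h and 5.52 and 16.8 at 48 h, with 1 called over the list alone at each time.

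Genes that differed at 24 h mostly differed in the same direction at 48 h. Among 10960 genes tested at both times, 1120 were higher at both, against 376 for independent lists of these sizes, and 1223 were lower at both, against 489. These are 76.1% of the genes higher at 24 h and 78.2% of those lower at 24 h. The cell lines are shared by both comparisons, so part of the excess may come from differences between the lines. Of the 2343 genes called in the same direction, 1961 (83.7%) had the larger change at 48 h, as for Hexim1, Cdkn1a and Kit.

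Over time, wild type cells differed little and floxed cells more, in comparisons for which no test was analysed here. From 24 h to 48 h, 102 expressed genes differed by at least 2-fold in wild type cells, 42 upward and 60 downward (154 with a pseudocount of 0.1), with a median absolute log2 change of 0.06. In floxed cells 689 did, 536 upward and 153 downward, with a median absolute change of 0.32, and that count was 1134 with a pseudocount of 0.1 and 319 with a pseudocount of 5. In wild type cells the interferon list had a median of -0.68 and the monocyte and macrophage list -0.64, both at percentile 0, the granulocyte list -0.17, also at percentile 0, and the cholesterol synthesis list 0.28, at percentile 100. Smaller medians outside the random range were -0.11 for immediate early genes (percentile 0.01), -0.10 for histones (0.085), -0.05 for Myc targets (2.37), 0.02 for amino acid and ER stress genes (98.3), 0.06 for stem and progenitor genes (98.3) and 0.09 for glycolysis (100). Saa3, an acute phase protein, stood at 11.8 FPKM at 24 h and 2.09 at 48 h in wild type cells, and Creb3l2, a membrane-bound transcription factor, at 2.76 and 5.08. In floxed cells the interferon list had a median of 0.70, the monocyte list 0.72, the granulocyte list 0.73 and immediate early genes 0.75, all at percentile 100, and p53 targets 0.40 (percentile 99.99). On the lower side, Myc targets had a median of -0.56 (percentile 0) and DNA replication genes -0.37 (percentile 0.26). Marcksl1, a membrane-associated actin regulator, stood at 48.1 and 578 in floxed cells, against 32.3 and 34.4 in wild type cells. Scd1 and Fads2, both fatty acid desaturases, were 5.11- and 2.67-fold lower at 48 h than at 24 h in floxed cells.

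The change of the genotype difference between the times cancels whatever differed constantly between the lines. It was at least 2-fold for 926 genes, 722 upward and 204 downward (1448 with a pseudocount of 0.1 and 429 with a pseudocount of 5), again with no test. Its size on the log2 scale was 3.73 for Saa3, 3.66 for Mmp9, 3.56 for Ccdc80, 3.47 for Marcksl1, 3.43 for Isg15, 2.90 for Ifi27l2a, 2.87 for S100a9 and 2.85 for the stress-induced factor Atf3. In the other direction it was -2.34 for Scd1, -1.91 for Fads2, -1.56 for Cited4, -1.54 for Ak4, -1.53 for Spred1, which restrains Ras signalling, and -1.48 for Igfbp4 and for Slco3a1. Among the lists, the median was 1.51 for monocyte and macrophage genes, 1.47 for interferon response genes, 1.02 for granulocyte genes, 0.88 for immediate early genes and 0.40 for p53 targets, all at percentile 99.98 or above. It was -0.48 for Myc targets (percentile 0), -0.36 for DNA replication genes (percentile 0.47) and -0.35 for cholesterol synthesis genes (percentile 1.44). A change of wild type cells over time does not cancel in this difference. For monocyte and interferon genes the wild type medians over time were -0.64 and -0.68, and the floxed ones 0.72 and 0.70. For cholesterol synthesis genes the wild type median was 0.28 and the floxed one -0.13.

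**Figure D3:**
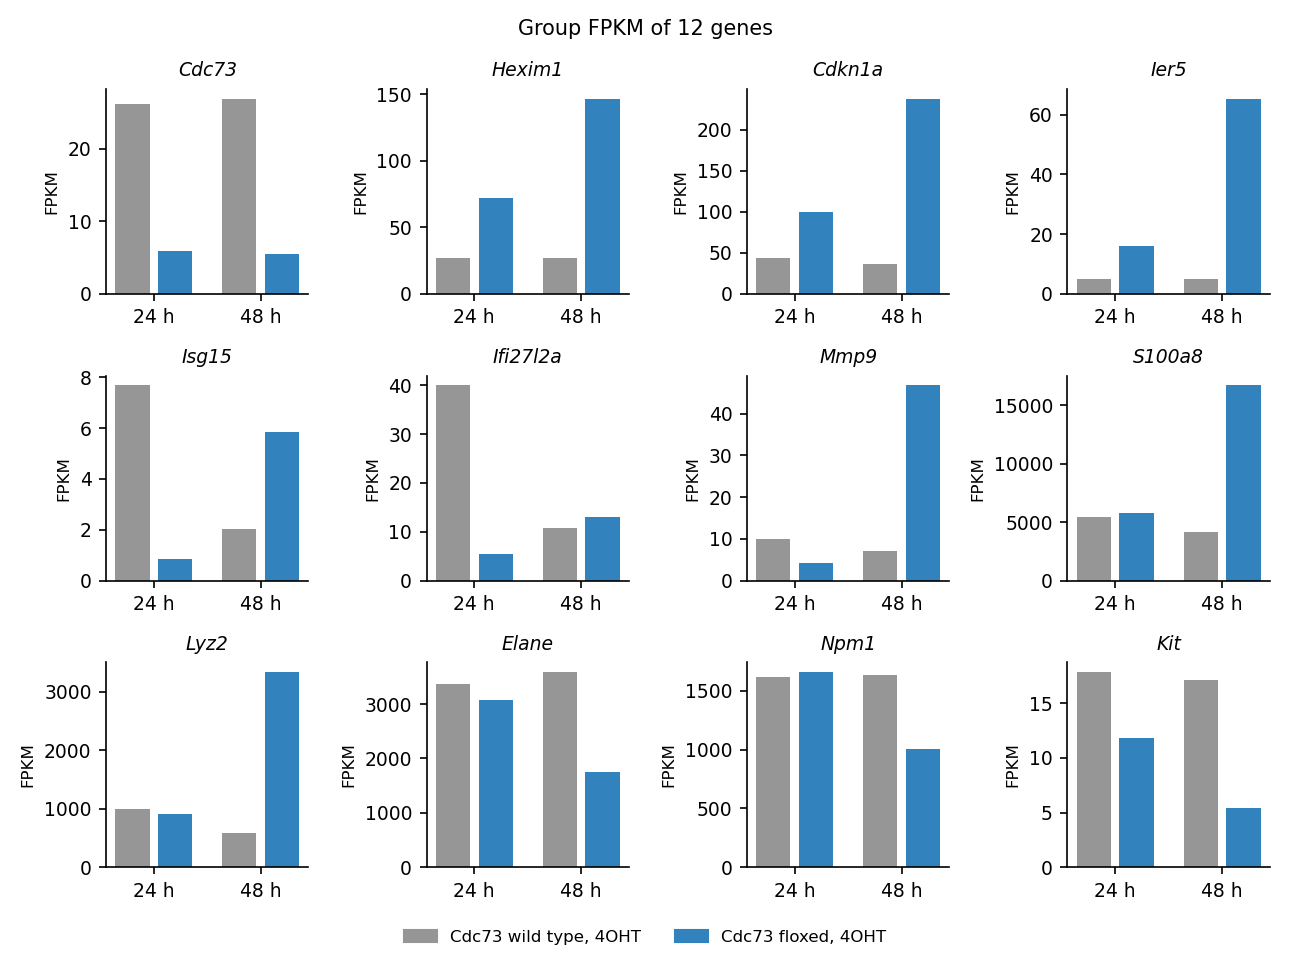
Bars give the authors' group FPKM of 12 genes in wild type (grey) and floxed (blue) cells after 24 h and 48 h of 4OHT, each on its own axis starting at 0, without error bars because the table holds 1 value per group. Cdc73 lay at 22.7% and 20.3% of wild type, and S100a8 reached 16678 in floxed cells at 48 h against 4134 in wild type cells.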

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

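Of the tests in this part, those of scaling between the times and of a larger share of monocyte-like cells were chosen after the result was seen. The difference between the times has no test here, so the counts in opposite directions rest on the authors' call at each time and were not themselves tested.

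The genotype difference turned direction with time for some genes. Lower in floxed cells at 24 h and higher at 48 h were 118 genes, and higher at 24 h and lower at 48 h were 18. The 118 included 9 interferon response genes, 5 monocyte and macrophage genes and 4 granulocyte genes. Isg15, for example, went from 7.67 in wild type and 0.831 in floxed cells at 24 h to 2.02 and 5.86 at 48 h, S100a9 from 2574 and 1166 to 1993 and 6618, and Mmp9 from 9.90 and 4.12 to 7.01 and 46.7. The lipocalin gene Lcn2 (117 and 80.5, then 94.7 and 445) and the myeloperoxidase gene Mpo, one of the 18 (1145 and 1986, then 1368 and 1011), were chosen after their values were seen.

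The interferon response list was lower in floxed cells at 24 h and its wild type level was higher at 24 h than at 48 h. A shift of scale between the times would move all genes, but the median log2 change of expressed genes in wild type cells was -0.011. A level raised in the wild type cells at 24 h alone would leave floxed cells at 24 h level with wild type cells at 48 h. The list median of that ratio was -0.31, below the range of random lists from -0.13 to 0.21, although nearer to 0 than the -1.03 against wild type cells at 24 h. That range does not allow for genes of a list moving together. This list moved by -0.68 between the wild type groups, so the comparison cannot decide whether such a raised level is the cause. A larger share of monocyte-like cells in the wild type culture at 24 h stays open: the monocyte list was also low in floxed cells at 24 h (percentile 0.03) but less so, with a difference of the medians, interferon minus monocyte, of -0.78 (bootstrap interval -1.30 to -0.48), whereas over time in wild type cells the medians were -0.68 and -0.64 (difference -0.04, interval -0.35 to 0.14). Open too are a lower interferon response after loss of Cdc73, as a hypothesis, and, untested, a difference between the lines that existed before 4OHT or between the cultures of a day.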

How the results depend on the processing

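No paired analysis was possible because the deposited columns carry 1 value per group and no replicate values. For the same reason the limma fit without a trend, the replicate block, the block within each genotype, the fit of only the libraries compared, leaving out each library, and DESeq2 on counts were not run. The 5 added lists were not recomputed. Pseudocounts and scalings do not reach the authors' q, so they were run on sizes and list medians. The settings of q under 0.01, joint adjustment and left-out gene types or genes were chosen after the data were seen.

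No named called gene and no list that stood apart changed direction. Of the medians within the random range, 8 changed sign under at least 1 alternative, with 11 values of at most 0.034 in size. These were MLL fusion genes at 24 h (-0.03 with no filter, -0.0089 under quantile normalization), PAF1 complex (-0.01) and elongation factors (-0.02) at 48 h and Myc targets at 24 h (0.0089) with groups rescaled, glycolysis at 24 h under quantile normalization (0.01), ribosomal proteins at 48 h with TMM factors (0.0099), and histones (0.03 with no filter, 0.00097 rescaled) and granulocyte genes (0.03 at 5 FPKM or more, 0.0057 rescaled) at 24 h. Rescaling and TMM factors move nearly all genes together, so a change of sign under them says little about a list. With groups rescaled, the percentile went from 73.7 to 73.9 for the PAF1 complex, 88.3 to 88.7 for elongation factors and 58.6 to 58.9 for Myc targets. Without a change of sign, 12 values of 8 medians standing apart and 34 of 15 others moved by over 1.5 times, among the latter the 48 h medians of MLL fusion genes at 5 FPKM or more (-0.0090) and megakaryocyte genes with a pseudocount of 5 (0.30) or no filter (0.27). The range over the alternatives was 0.18 to 0.53 for interferon genes, 0.08 to 0.25 for histones, -0.22 to -0.05 for mitosis, -0.02 to 0.15 for elongation factors, -0.01 to 0.16 for the PAF1 complex and -0.17 to 0.0099 for ribosomal proteins at 48 h. At 24 h it was 0.0026 to 0.21 for megakaryocyte genes, -0.03 to 0.07 for MLL fusion genes, -0.05 to 0.03 for histones, -0.04 to 0.01 for glycolysis, -0.04 to -0.02 for DNA replication, -0.01 to 0.03 for granulocyte genes and -0.01 to 0.0089 for Myc targets. Of the results that answer a comparison, 364 values under alternatives stayed on their side of the threshold or within 1.5 times, as did 1412 values of single genes, scaling medians and shares. The rest moved as follows. The pseudocount, which weights low genes, changed the counts of at least 2-fold by its construction. Called genes at 24 h were 347 as reported, 657 with a pseudocount of 0.1 and 119 with 5, and at 48 h 1705 as reported and 755 with 5. The change of the genotype difference gave 926 as reported, 1448 and 429, floxed cells over time 689, 1134 and 319, and wild type cells over time 102, and 154 with 0.1. Requiring a log2 change of at least 1 besides q left 347 genes at 24 h, 1705 at 48 h and 246 called in the same direction at both, against 3037, 6267 and 2343, and q under 0.01 left 1997 at 24 h and 1521 at both, fewer by construction. Among the lists, megakaryocyte genes at 48 h stood apart with a pseudocount of 0.1 (2.74). Respiratory chain genes at 48 h came within the random range with a pseudocount of 5 (-0.14), no filter (-0.17) and without genes of similar large difference (-0.14). Stem and progenitor genes at 48 h did so at 5 FPKM or more (-0.60), and ribosomal protein genes at 24 h under quantile normalization (-0.048). For these lists the cause was not tested.

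Adjusting p over both times together gave 3339 calls at 24 h and 6069 at 48 h, and leaving out small RNAs, pseudogenes and genes sharing a locus entry gave 2623 and 5388. Rescaling every group to the same sum moved the median of all genes at 48 h from -0.06 to -0.16. Relative depth differed by at most 1.27 times between groups if the most common ratio of low values, which 72 of 1339 genes lie near, comes from single fragments. Absolute depth is unknown, and low genes rest on few fragments, so folds of genes near 1 FPKM are imprecise.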

Other observations

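Of the tests in this part, the 3 on chromosome 1, mRNA length and expression level were written before their results were seen, and the other 3 after. The 5 gene lists in the next paragraphs were added after the data were seen, so their direction is not independent evidence.

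Genes of eosinophil granules were higher in floxed cells at both times, with 6 of 8 higher and 0 lower at each time (6 adjusted over the list alone). The peroxidase gene Epx stood at 0.0526 in wild type and 11.6 in floxed cells at 24 h and at 0.0331 and 5.49 at 48 h, and Prg3 at 0.362 and 4.69 at 24 h. The list's median log2 change was 3.03 at 24 h and 2.75 at 48 h. Its median change of the genotype difference between the times was 0.04 (percentile 70.4). Prg2 and Ear1 belong to the set of similar large difference described below. A difference between the lines that existed before 4OHT therefore stays open for this list. S100 and stefin genes had 6 higher and 2 lower of 13 at 24 h and 12 higher and 1 lower at 48 h (9 and 13 over the list alone), with medians of 0.35 and 1.82. S100a6 was 3.34-fold higher at 24 h and 20.3-fold at 48 h, S100a4 3.18- and 14.4-fold, and Stfa2l1 2.23- and 6.33-fold. MHC class I genes had 6 higher and 4 lower of 13 at 24 h and 5 higher and 2 lower at 48 h (10 and 7 over the list alone; medians 1.08 and 1.66). H2-K1 was 1.45-fold higher at 24 h and 4.16-fold at 48 h, but reads of this family are hard to assign, and 6 of the members share a locus entry.

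Inhibitors of cyclin-dependent kinases were mostly higher at 48 h. Of 6, 3 were higher and 2 lower at 24 h and 5 higher and 1 lower at 48 h (6 over the list alone at each time; medians 0.48 and 1.58). Cdkn1c, the inhibitor p57, stood at 1.14 and 6.60 FPKM at 24 h and 1.09 and 30.0 at 48 h, Cdkn1b was 2.82-fold and Cdkn2d 3.56-fold higher at 48 h, and Cdkn2a was 1.76- and 1.52-fold lower. Of 5 D type cyclins and their kinases, 1 was higher and 1 lower at 24 h and 2 higher and 3 lower at 48 h (3 and 5 over the list alone; medians -0.16 and -0.78). Ccnd3 was 3.41-fold higher and Cdk4 1.94-fold lower at 48 h, while Ccnd2 stood at 9.30 and 0.794. Within the list of MLL fusion targets, and chosen after their values were seen, Hoxa5 was 1.71-fold higher at 24 h and 5.10-fold at 48 h, Hoxa9 1.27- and 1.45-fold, and Id2, higher at both times, 9.96-fold at 48 h, while Bcl2 was lower at 1.16 in wild type and 0.635 in floxed cells at 24 h and 1.18 and 0.336 at 48 h. Ccnd2, Ccnd3 and Hoxa5 share their locus entry with another gene, so their values are uncertain.

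A set of 23 genes, 17 higher and 6 lower, was called in the same direction at both times with differences of similar large size. In each, the genotype difference was at least 2 on the log2 scale at both times and moved by under 0.5 between them. For 2 pairs at 1 locus, Eno1 with Gm5506 and Ndufs5 with BC002163 (Eno1 and Gm5506 chosen after their values were seen), the summed FPKM differed by at most -0.34 between the lines, which is consistent with reads assigned to a different member of the pair. A chromosome segment carried along with the targeted allele is argued against for the set, since 1 of 23 genes lies on chromosome 1 (4.35%, upper limit 21.9%). Pseudogenes or shared loci made up 12 of 23 (52.2%, limits 30.6% to 73.2%), which leaves open whether they explain most of the set. Loss of Cdc73 and differences between the lines that existed before 4OHT stay open, as untested, because no untreated library was analysed here.

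Long genes were lower than short genes in floxed cells at 48 h: the 2618 genes with the longest annotated spans, of at least 49.1 kb, had 526 higher and 982 lower, and the 2618 shortest, of at most 9.15 kb, 812 higher and 553 lower. The median log2 change was -0.16 in the longest and 0.10 in the shortest genes, so short genes were higher as well as long genes lower. The medians differed by -0.26 on the log2 scale (bootstrap interval over genes -0.31 to -0.21), and by -0.01 at 24 h. The intervals in this paragraph describe spread among genes, not between cultures. Within bins of equal mRNA length 75.3% of the difference was kept (65.7% to 100%), and within bins of equal expression 93.6% (81.5% to 111%), which argues against either as the whole cause. In wild type cells the difference from 24 h to 48 h was -12.1% of that in floxed cells (-15.7% to -8.99%), so time in culture with 4OHT does not give it either. A candidate explanation is a defect in transcribing long genes after loss of an elongation complex subunit, a hypothesis found on the same data and not itself tested. Whether the gene lists that were higher at 48 h account for part of the difference was not tested. Differences in RNA quality between cultures were not tested either.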
